A study of Mus musculus with 12 samples.

How the data were processed

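RNA was measured in BV2 cells, an immortalised line of mouse microglia, which are the resident macrophages of the brain. Per the labels, Spi1 was either lowered transiently with a short hairpin RNA or raised transiently from a cDNA, and the cells were sorted by flow cytometry before RNA was taken. The 12 libraries form 4 groups of 3: scrambled controls and Spi1 knockdown in 1 experiment, empty controls and Spi1 overexpression in the other. Groups came from the treatment labels and the numbers 1 to 3 from the sample titles. The labels do not say whether libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Per the labels' protocols, polyA RNA was made into libraries with a TruSeq v2 kit, which does not mark strand, and read on a HiSeq instrument as single reads of 100 bases.

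The authors deposited 2 tables of FPKM, which is reads per kilobase of gene and per megaread of the library, with 1 column per library and 24062 entries named by gene symbol. The submitters' processing notes name CASAVA 1.8.2, bcl2fastq, STAR 2.5.2a, featureCounts and DESeq2 1.14, and the genome build mm10, without saying what each was used for. The gene annotation, the length behind each FPKM value and any strand setting are not given in the sources used here. The unit is not stated either and was read from the values: within a gene, every value was a whole multiple of a step, and the ratio of steps between libraries was the same for all genes. Each library's values are therefore scaled by its own read total, so a large change in a few abundant genes shifts every other gene a little. The same scaling holds in the 2 tables, and it does not remove a shift between the experiments.

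Whole reads were recovered from these steps for 17842 of the 17842 genes above 0, 6 of them by a search over lengths. Among the 14111 genes above 0 in 10 or more libraries, 14110 gave a gene length that was whole within 0.01 base, and 744 recovered lengths equalled the exon length in GENCODE M21. Another 83 genes were rescaled to a whole length, and 1030 genes have reads of uncertain scale. The recovered reads gave depths of 22.3 to 33.1 megareads per library and were used for depth, for CPM and for limma-voom alone. As the deposited unit is FPKM and not counts, the count models planned for a table of counts were not run, and the test set out beforehand for normalised values took their place.

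Each experiment was tested by itself with limma 3.58.1 in R 4.3.3, on log2(FPKM + 1), without trend or robust options. Genes with a mean of at least 1 FPKM over the 6 libraries of an experiment were tested, and p-values were adjusted by the Benjamini-Hochberg (BH) method over all of these, with a threshold of 0.05. A log2 fold change is on the log2(FPKM + 1) scale and understates the change of genes at low levels. The difference between the effects, overexpression minus knockdown, was tested as an interaction over all 12 libraries with 4 group means and 1 shared spread. The 2 experiments share no control library. Symbols used more than once, 4 entries in all, were left out.

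The test, the gene lists, the alternatives and the rule for naming genes were set before the data were examined. That rule takes Spi1, then the 10 largest rises and 10 largest falls among called genes whose 3 treated libraries all lie on 1 side of the 3 controls and whose mean log2 CPM is at least 1. Predicted genes, clone names, pseudogenes, unnamed or accession-like IDs and symbols turned into dates were skipped. For the difference the 10 largest of each sign were taken without the condition on separation. From each list up to 4 called members with the smallest p were admitted, or 2 as values that did not pass. Among genes called in both experiments, up to 10 opposite and 5 same-direction ones per kind were admitted. Some genes that the rule takes are not reported here.

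Of 36 lists, 26 had 5 or more tested members and were tested with camera in limma, at a preset correlation of 0.01 between genes, with BH adjustment over the 26. The same test with an estimated correlation was run beside it, as was fry, which asks whether the genes of a list move 1 way on balance and does not compare them with other genes. The other lists are 9 sets of markers of other cell types, which were summed, and the mitochondrially encoded mRNAs, a list that is void because none of its 13 symbols was found in the tables. Ms4a4a and Ly6g were not found under these symbols. Ifit3b, Adgre1 and Lilrb4a were matched through RefSeq synonyms to I830012O16Rik, Emr1 and Lilrb4.

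Libraries with the same number deviated together from their group means. The correlation across genes of these deviations was 0.397, 0.540 and 0.345 for numbers 1, 2 and 3 of the knockdown experiment, and 0.791, 0.845 and 0.513 in the overexpression experiment. All were above the limit of 0.1 set for treating numbers as pairs, so values with the number as a block are given beside counts and list calls that they change; the pairing comes from the data, since the labels do not explain the numbers.

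Alternatives covered median-of-ratios scaling, limma-voom on the recovered reads, the replicate block, all 12 libraries in 1 fit, pseudocounts of 0.1 and 10, no filter on low values or a filter of 1 CPM in 3 libraries, stricter thresholds, and each library left out in turn. Combinations of the block with another scaling, a trended prior and fits without the libraries numbered 2 were added after seeing the data.

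Gene positions came from GENCODE M21 on GRCm38, the assembly also called mm10. Of 164 named genes, 163 matched 1 gene, and 44 of these share exon bases with another gene, 38 with a gene on the opposite strand. Reads of such pairs, and of close relatives such as the H2-Q, Pira and Pirb, Lilrb4, Stfa and Ms4a genes, cannot be told apart with certainty.

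The tests were tried on simulated data with 200 changed genes. The simulated libraries kept the shared deviations of same-numbered libraries, so a gain from the block was built in. Far fewer genes were changed than were called in knockdown, so these shares do not carry over to the real counts. For knockdown, over 11098 genes, 47.0%, 84.9% and 95.5% of 1.5-fold, 2-fold and 4-fold changes were recovered, and 3 of 153 calls were false; with the block these were 59.1%, 90.9% and 87.9%, and 15 of 172 calls were false, or 8.72%. For overexpression, over 11154 genes, these shares were 10.6%, 59.7% and 95.4%, or 63.6%, 91.0% and 93.9% with the block, and 0 of 109 and 6 of 170 calls were false. For the difference, over 11005 genes, 17.6%, 68.7% and 89.2% were recovered. Recovery and plots used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.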

Results

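The data were RNA sequencing libraries of BV2 cells, an immortalised line of mouse microglia, in which Spi1 had been lowered or raised transiently before sorting. Spi1 encodes PU.1, a transcription factor of the ETS family that myeloid cells need for their identity. The series title ties PU.1 levels to the inflammatory response of microglia and to Alzheimer's disease, and the design asks what lower and higher Spi1 do to the transcriptome. There were 4 groups with 3 libraries each: scrambled controls, Spi1 knockdown, empty controls and Spi1 overexpression. Knockdown and overexpression had separate controls and were deposited as 2 tables of FPKM. Reads on genes in M (megareads), recovered from the steps in the values, came to 25.8, 24.6 and 24.4 in the scrambled controls and 26.6, 26.7 and 33.1 in knockdown. They came to 22.3, 23.9 and 27.8 in the empty controls and 29.8, 27.7 and 29.1 in overexpression. Between 14871 and 15492 genes were above 0 in a library.

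Spi1 lies on chromosome 2, bases 91082390 to 91115756 of the plus strand in mm10, with 2695 exon bases in 7 blocks and no other annotated gene over its exons. Its level was 159, 169 and 168 FPKM in the 3 scrambled controls and 50.9, 42.5 and 52.3 FPKM in the 3 knockdown libraries. The means were 165 ± 5.41 and 48.5 ± 5.32 FPKM (SD, n = 3 each), a log2 fold change of -1.75 with a standard error of 0.0891 (limma, Benjamini-Hochberg, BH, adjusted p = 0.000697). In the other experiment Spi1 was at 158, 117 and 131 FPKM in the empty controls and at 287, 224 and 206 FPKM in overexpression. These means were 135 ± 20.8 and 239 ± 42.3 FPKM, a log2 fold change of 0.81 with a standard error of 0.165. The targeted gene moved the way the labels state in every pair of same-numbered libraries.

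**Figure D1:**
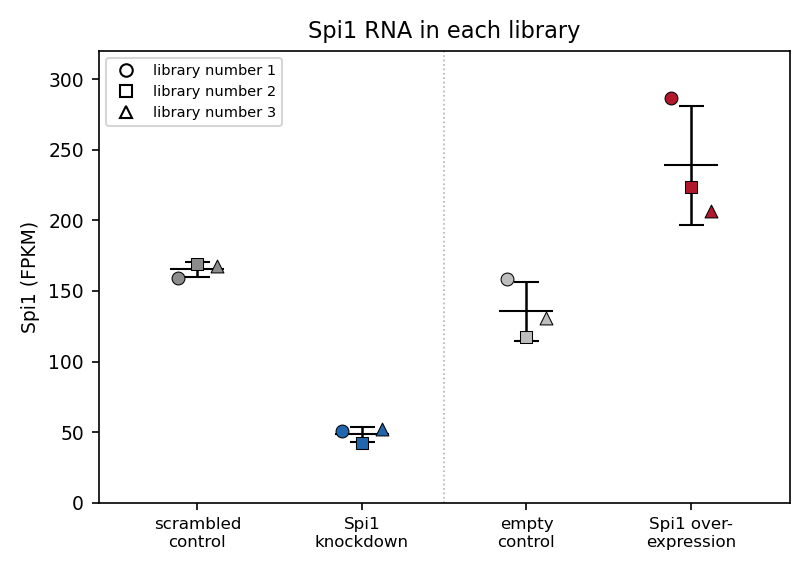
Spi1 RNA in FPKM (vertical axis) in each of the 12 libraries, by group. Points are libraries with the shape giving the library number, and bars are the mean ± SD of 3 libraries; knockdown libraries sit between 42.5 and 52.3 FPKM and overexpression libraries between 206 and 287 FPKM.

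With Spi1 lowered, textbook PU.1 target genes fell in 26 of 37 tested members, with a median log2 fold change of -0.49. Genes of the G2/M phase of the cell cycle rose in 32 of 33 members, with a median of 0.94. As lists both passed in camera with a preset correlation between genes, but not with an estimated correlation (limma, BH adjusted p = 0.122 and 0.318 with an estimated correlation). Against the empty controls of the other experiment, the G2/M median was -0.80 in the scrambled controls and 0.11 in knockdown. Low scrambled controls therefore cannot be told apart from a rise of G2/M genes in knockdown. Hp, which encodes the haemoglobin-binding protein haptoglobin, rose furthest among the named genes, from 7.08 ± 2.12 to 73.4 ± 7.04 FPKM. Clec4n, which encodes the fungal pattern receptor dectin-2, fell furthest, from 15.6 ± 2.06 to 3.14 ± 0.384 FPKM (SD, n = 3 in each group of these genes).

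Of 11214 genes tested, 2945 passed an adjusted p of 0.05 in limma with BH adjustment, 1952 of them higher and 993 lower in knockdown, and 85 of the 2945 changed at least 2-fold on the fitted scale. With median-of-ratios scaling 2705 genes passed, 1251 higher and 1454 lower, so the excess of higher over lower calls turned with the scaling. The 3 knockdown libraries lay outside the range of the 3 controls in 45.4% of genes, 3401 above and 1691 below, against 10% by chance. With the replicate number as a block 5081 genes passed. This fit made 15 false calls of 172 in simulated data with 200 changed genes, a share that does not carry over to 5081 calls. Leaving out knockdown library 1, 2 or 3 left 1905, 1708 or 1458 genes, and leaving out both libraries numbered 2, a choice made after seeing the data, left 449, of which 441 were among the 2945.

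Among the other large falls, Igsf6, an immunoglobulin-domain membrane protein gene, fell from 21.95 ± 5.27 to 5.50 ± 0.463 FPKM (limma, BH adjusted p = 0.00150), and Il1f9, a cytokine gene of the interleukin-1 family, went from 12.6 ± 2.27 to 2.90 ± 0.497 FPKM (limma, BH adjusted p = 0.00115). Ccl7 and Ccl12, genes of chemokines that attract monocytes, had log2 fold changes of -1.79 and -1.56, with Ccl7 at 484 ± 99.3 against 138 ± 19.9 FPKM. Pirb, an inhibitory receptor gene, and Ms4a6d, a membrane protein gene, fell by 1.56 and 1.54 on the log2 scale, and Il1rn, the gene of the interleukin-1 receptor antagonist, by 1.52. Nos2, the gene of inducible nitric oxide synthase, fell by 1.91 with scattered controls of 87.4 ± 53.8 FPKM (limma, BH adjusted p = 0.0280). This call was lost without scrambled control 1 (adjusted p = 0.0605), knockdown 2 (0.0733) or knockdown 3 (0.0797). Csf3, the gene of granulocyte colony-stimulating factor, fell by 1.78 (limma, BH adjusted p = 0.0277), and the call was lost without scrambled control 1 (adjusted p = 0.0692) or 2 (0.0674). In each of these genes, and in each gene said below to rise or fall without the block, the 3 knockdown libraries lay on 1 side of the 3 controls. For Ccl12, Nos2 and Csf3 the knockdown level was near that of the empty controls of the other experiment. High scrambled controls therefore cannot be told apart from a fall in knockdown for them, and a shift between experiments would enter this comparison.

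Among the other large rises, Uchl3, a ubiquitin hydrolase gene, went from 12.6 ± 0.948 to 38.5 ± 3.01 FPKM (limma, BH adjusted p = 0.000697). Ccnb2, Plk1, Kif2c and Cdc20, all genes of mitosis, rose by 1.41, 1.29, 1.15 and 1.15 on the log2 scale, and Lmnb1, the gene of the nuclear lamina protein lamin B1, by 1.22. Sapcd2 rose by 1.27, Pdcd1, the gene of the inhibitory receptor PD-1, also by 1.27 from 1.52 ± 0.506 FPKM, and Klhl30 went from 0.664 ± 0.197 to 2.80 ± 0.0619 FPKM. The adjusted p-values of these 8 genes lay at or below 0.00675 in limma with BH adjustment.

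Among textbook PU.1 target genes 26 of 37 members fell and 2 rose, or 28 and 2 when adjusted over the list alone (camera in limma, BH adjusted p = 6.88e-16, and adjusted p = 0.122 with an estimated correlation). Ncf1, a subunit gene of the phagocyte NADPH oxidase, went from 104 ± 10.5 to 52.5 ± 0.980 FPKM, Msr1, a scavenger receptor gene, had a log2 fold change of -1.07, and Ptprc, the gene of CD45, -0.59. The members that rose were Cebpa, at 0.31, and Emr1, the gene of F4/80, at 0.74. Emr1 was named after its value was seen, as were Saa3, Tlr3, Lamp1, Axl, Zcwpw1 and Cdc25b below. These were not refitted without single libraries. Complement and Fc receptor genes fell in 7 of 17 members, or 8 adjusted over the list alone, with a median of -0.23 (camera in limma, BH adjusted p = 3.91e-06, and adjusted p = 0.238 with an estimated correlation). They included Itgam, the gene of the complement receptor subunit CD11b, at -1.12, Fcgr1 at -0.90 and C3ar1 at -0.76. Genes of chemokine receptors and migration fell in 8 of 20 members, and in 8 adjusted over the list alone, with a median of -0.31 (adjusted p = 0.000213, and adjusted p = 0.131 with an estimated correlation, both by camera in limma with BH adjustment). Plaur, the urokinase receptor gene, fell by 0.85, P2ry6, a receptor gene for extracellular UDP, by 0.77, and Ptafr, the platelet-activating factor receptor gene, by 0.75. With the replicate block 11 genes of this list fell and 3 rose.

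Phagocytosis and lipid uptake receptors fell in 5 of 23 members and rose in 2, with the same counts adjusted over the list alone and a median of -0.13 (camera in limma, BH adjusted p = 0.00404, and adjusted p = 0.485 with an estimated correlation). Cd300lf, a phosphatidylserine receptor gene, fell by 0.84 on the log2 scale, while Axl, a receptor tyrosine kinase gene of apoptotic cell uptake, rose by 0.77. Genes of MHC class II presentation fell in 3 of 8 members, or 4 adjusted over the list alone, with a median of -0.35 (camera in limma, BH adjusted p = 0.00211, and adjusted p = 0.122 with an estimated correlation). They were Cd86 and Cd80, which encode costimulatory ligands of T cells, at -0.95 and -0.76, and the cathepsin gene Ctss at -0.47. In the blocked test 9 phagocytosis genes fell and 3 rose, and 5 MHC class II genes fell and 1 rose. With median-of-ratios scaling 5 phagocytosis genes fell and 0 rose, so the call of Axl was lost.

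The list of NF-kB and inflammatory cytokine genes fell in 14 of 32 members and rose in 1, Saa3, with the same counts adjusted over the list alone and a median of -0.21 (camera in limma, BH adjusted p = 4.69e-07, and adjusted p = 0.122 with an estimated correlation). Ccl2, a monocyte chemokine gene, went from 1355 ± 173 to 714.0 ± 26.8 FPKM. Against the empty controls of the other experiment, the NF-kB median was 0.25 in scrambled controls and -0.01 in knockdown. For complement and Fc receptor genes these medians were 0.24 and -0.04. The medians were 0.16 and -0.08 for MHC class II, 0.19 and -0.11 for chemokine receptor and 0.12 and -0.06 for pattern recognition genes. They were 0.10 and -0.08 for lysosomal genes and 0.14 and 0.04 for disease-associated markers. High scrambled controls therefore cannot be told apart from a fall in knockdown for these lists, and a shift between experiments would enter this comparison. Knockdown lay further from the empty controls in the PU.1 target, stress response, phagocytosis and Alzheimer's disease lists. In the other lists that passed as lower, the scrambled controls lay further. Pattern recognition receptors and adaptors fell in 12 of 28 members and rose in 1, Tlr3, or 13 and 1 adjusted over the list alone, with a median of -0.15 (camera in limma, BH adjusted p = 9.65e-07, and adjusted p = 0.136 with an estimated correlation). Besides Clec4n these included Clec4d at -0.82, Cd14, the co-receptor gene for lipopolysaccharide, at -0.64, and Tlr13 at -0.55. Type I interferon response genes fell in 4 of 48 members, and in 4 adjusted over the list alone, with a median of -0.08 (camera in limma, BH adjusted p = 0.00368, and adjusted p = 0.668 with an estimated correlation). Ifit2, an antiviral gene, fell by 0.81. The share of interferon genes that fell is near that of all tested genes, 993 of 11214. The same holds for the glycolysis genes below, and for the rise of MHC class I genes against 1952 of 11214. Of the interferon genes 7 fell with median-of-ratios scaling, 8 fell in limma-voom, and 12 fell and 1 rose with the block. The blocked counts were 16 fallen and 3 risen for NF-kB genes and 13 and 2 for pattern recognition. The interferon list's call was lost without scrambled control 2 (adjusted p = 0.218) or knockdown 3 (0.0548).

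Lysosomal genes fell in 15 of 37 members and rose in 1, Lamp1, or 19 and 2 adjusted over the list alone, with a median of -0.23 (camera in limma, BH adjusted p = 6.50e-08, and adjusted p = 0.122 with an estimated correlation). Lipa, the gene of lysosomal acid lipase, went from 139 ± 18.7 to 80.7 ± 3.88 FPKM, and the proton pump subunit genes Atp6v0d1 and Atp6v1a had log2 fold changes of -0.59 and -0.46. Integrated stress response genes fell in 9 of 21 members, or 10 adjusted over the list alone, with a median of -0.21 (camera in limma, BH adjusted p = 6.61e-06, and adjusted p = 0.122 with an estimated correlation). Psph, an enzyme gene of serine synthesis, fell by 1.36 and Slc7a11, the cystine transporter gene, by 1.04. Genes of glycolysis and hypoxia fell in 2 of 27 members and rose in 1, also adjusted over the list alone, with Pgk1, a glycolytic enzyme gene, at -0.46, and a median of -0.09 (camera in limma, BH adjusted p = 0.00218, and adjusted p = 0.131 with an estimated correlation). Cholesterol biosynthesis genes rose in 12 of 23 members, and in 12 adjusted over the list alone, with a median of 0.29 (camera in limma, BH adjusted p = 0.00219, and adjusted p = 0.318 with an estimated correlation). Insig1, a feedback regulator gene of this pathway, rose from 27.7 ± 2.74 to 51.3 ± 2.52 FPKM, and Idi1, Sqle and Cyp51, enzyme genes of the pathway, rose by 0.45, 0.39 and 0.36. Under the replicate block 24 lysosomal genes fell and 2 rose, 13 stress response genes fell and 2 rose, 7 glycolysis genes fell and 2 rose, and 14 cholesterol genes rose and 1 fell. With median-of-ratios scaling 5 glycolysis genes fell and 1 rose.

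G2/M genes rose in 32 of 33 members, and in 32 adjusted over the list alone, with Cdc25b as the member that did not pass (camera in limma, BH adjusted p = 5.85e-14, and adjusted p = 0.318 with an estimated correlation). Top2a, the gene of the topoisomerase that untangles chromosomes, went from 39.2 ± 5.78 to 77.0 ± 3.17 FPKM, Ccnb1, a mitotic cyclin gene, rose by 1.08 on the log2 scale and Ube2c by 1.12. Genes of G1/S and DNA replication rose in 21 of 33 members, or 24 adjusted over the list alone, with a median of 0.50 (camera in limma, BH adjusted p = 4.96e-07, and adjusted p = 0.458 with an estimated correlation). Mcm7, a helicase subunit gene, rose by 0.74 and Pole, a DNA polymerase gene, by 0.68. The empty controls belong to the other experiment, so a shift between experiments would enter any comparison with them. Against them the G2/M genes were lower in the scrambled controls in 33 of 33 members, with a median log2 difference of -0.80. In knockdown these genes stood at 0.11. For G1/S genes these medians were -0.37 and 0.08, and for textbook PU.1 target genes 0.20 and -0.30. Uchl3 likewise stood at 38.5, 38.2 and 39.1 FPKM in knockdown, empty controls and overexpression against 12.6 in the scrambled controls. Hp did not, at 6.26 FPKM in the empty controls against 73.4 in knockdown.

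**Figure D2:**
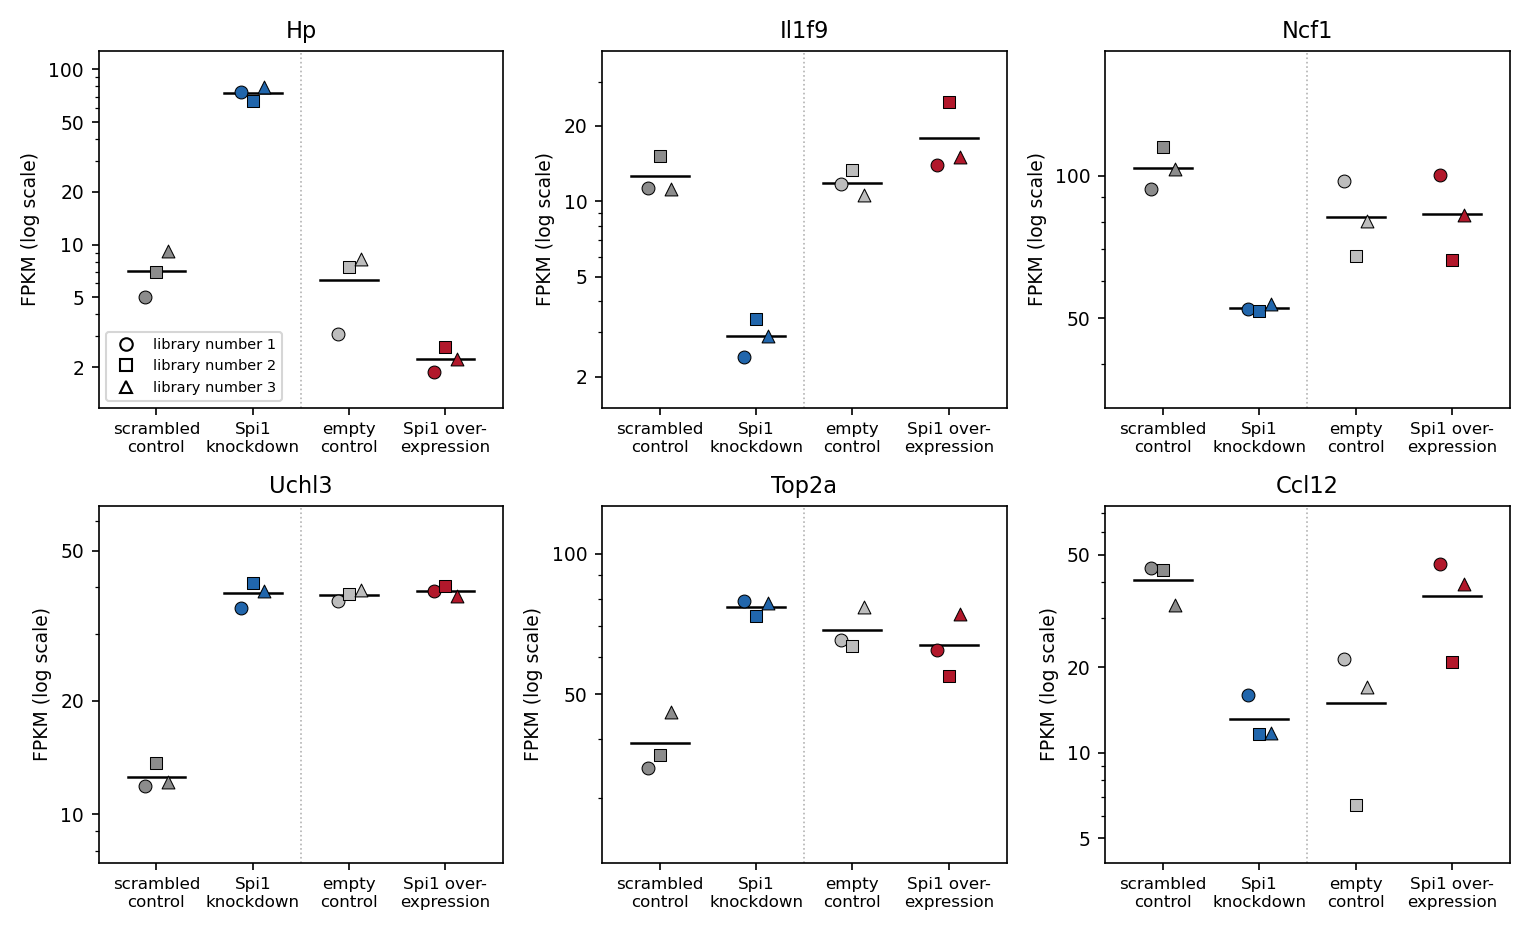
Levels of 6 named genes in FPKM (vertical axes, log scale) in each library, by group, with lines at the mean of 3 libraries and shapes for the library number. The dotted line parts the 2 experiments. Hp stands apart in knockdown (73.4 FPKM), Uchl3 in the scrambled controls (12.6 FPKM), and Ccl12 is lower in knockdown (13.1 FPKM) than in the scrambled controls (40.7 FPKM).

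Alzheimer's disease risk loci fell in 14 of 39 members and rose in 2, Mef2c and Zcwpw1, or 15 and 4 adjusted over the list alone, with a median of -0.12 (camera in limma, BH adjusted p = 6.61e-06, and adjusted p = 0.122 with an estimated correlation). Besides Ms4a6d, Pilrb1 fell by 1.02 and Sppl2a, an intramembrane protease gene, by 0.58, while Mef2c, a transcription factor gene, rose by 0.74. Disease-associated microglia markers fell in 7 of 29 members and rose in 5, or 8 and 5 adjusted over the list alone, with a median of -0.03 (camera in limma, BH adjusted p = 0.0123, and adjusted p = 0.533 with an estimated correlation). Clec7a, the gene of the beta-glucan receptor dectin-1, fell by 1.49 and Cd52 by 0.64, while Csf1, the gene of macrophage colony-stimulating factor, rose by 0.61. Homeostatic microglia markers fell in 2 of 11 members, among them Csf1r, the receptor gene for macrophage colony-stimulating factor, at -0.73, and rose in 1, with the same counts adjusted over the list alone and a median of -0.04 (camera in limma, BH adjusted p = 0.0412, and adjusted p = 0.370 with an estimated correlation). Macrophage transcription factors fell in 4 of 28 members and rose in 3, or 3 and 3 adjusted over the list alone, with a median of -0.13 (camera in limma, BH adjusted p = 0.00700, and adjusted p = 0.136 with an estimated correlation). With median-of-ratios scaling 9 disease-associated markers fell and 2 rose, and 8 macrophage transcription factors fell and 2 rose. With that scaling, and also in limma-voom, 2 homeostatic markers fell and 0 rose. With the block the fallen and risen were 11 and 6 disease-associated markers, 9 and 6 macrophage transcription factors, and 17 and 6 Alzheimer's disease loci, and 9 MHC class I genes rose. MHC class I genes rose in 4 of 21 members, and in 4 adjusted over the list alone, with a median of 0.15 (camera in limma, BH adjusted p = 0.0377, and adjusted p = 0.509 with an estimated correlation). H2-Q4 and H2-Q6, relatives whose reads are hard to tell apart, rose by 0.51 and 1.12. The call of the disease-associated list was lost without scrambled control 1 (adjusted p = 0.0893) or knockdown 3 (0.0523), and that of the homeostatic list without scrambled control 3 (0.0808) or knockdown 2 (0.125) and with median-of-ratios scaling (0.0722). That of the MHC class I list was lost without scrambled control 1 (adjusted p = 0.0742) or knockdown 1 (0.0712) and with median-of-ratios scaling (0.0582).

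Over 13 alternatives for each, the highest adjusted p of the 19 lists that passed lay between 0.393 and 0.668. The other 7 lists did not pass in knockdown. Cytosolic ribosomal protein genes had a median of 0.15 and 33 of 35 members above 0 (camera in limma, BH adjusted p = 0.0525), and the list passed with the replicate block (adjusted p = 0.00369, but adjusted p = 0.640 with an estimated correlation and the block). By gene, limma called 0 of the 35, with 4 at an unadjusted p under 0.05, limma-voom 0 and the blocked test 19, and the count adjusted over the list alone was 0. In the p53 target list Plk3 fell by 0.63 and Rps27l rose by 0.40. In all, 3 of 19 members fell and 1 rose, also adjusted over the list alone (camera adjusted p = 0.0872, limma with BH). In the unfolded protein response list 3 of 18 members fell, among them Xbp1 at -0.47, and 1 rose, Edem1 at 0.48, also adjusted over the list alone. Oxidative phosphorylation genes fell in 2 of 33 members, among them Sdhd at -0.48, and rose in 1, or 1 and 0 adjusted over the list alone. Other ETS factors rose in 2 of 15 members, among them Gabpa at 0.38, and fell in 1, and heat shock and immediate early genes rose in 3 of 19, among them Hsp90aa1 at 0.41, and fell in 2. Adjusted over the list alone these counts were 2 and 1, and 4 and 2. LXR targets rose in 1 of 14 members and fell in 2, and adjusted over the list alone limma called 0, with 6 at an unadjusted p under 0.05 and 4 called by limma-voom over all genes. For the unfolded protein response, LXR, ETS and heat shock lists the median was above 0, or below 0 with median-of-ratios scaling. Without passing, camera placed the members below other genes (camera in limma, BH adjusted p = 0.171, 0.441, 0.912 and 0.961). The heat shock list was placed above other genes with median-of-ratios scaling or the block (camera in limma, BH adjusted p = 0.913 and 0.932). The blocked test called 5 fallen and 3 risen p53 targets, 5 and 4 unfolded protein response genes, 3 and 6 oxidative phosphorylation genes, 3 and 4 LXR targets, 3 and 5 ETS factors, and 3 and 6 heat shock genes. With median-of-ratios scaling, oxidative phosphorylation genes fell in 4 members and LXR targets in 3, with none rising, 6 unfolded protein response genes fell and 1 rose, 3 ETS factors fell and 1 rose, and 3 heat shock genes fell and 2 rose. Exons of Ncf1, Itgam, Top2a, Cebpa, Pilrb1, H2-Q4, Csf1r, Psph, Prc1, Ube2c, Mcm7, Pole, Plk1, Cdc20, Idi1, Cyp51, Cd52, Gabpa and Plk3 overlap those of another gene in GENCODE M21, so part of their reads may belong to that gene. How such reads were counted is not known, since the annotation behind the values is not given. The overlap is largest for Itgam, which shares 3450 of 5024 exon bases with Gm49368 on the same strand.

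**Figure D3:**
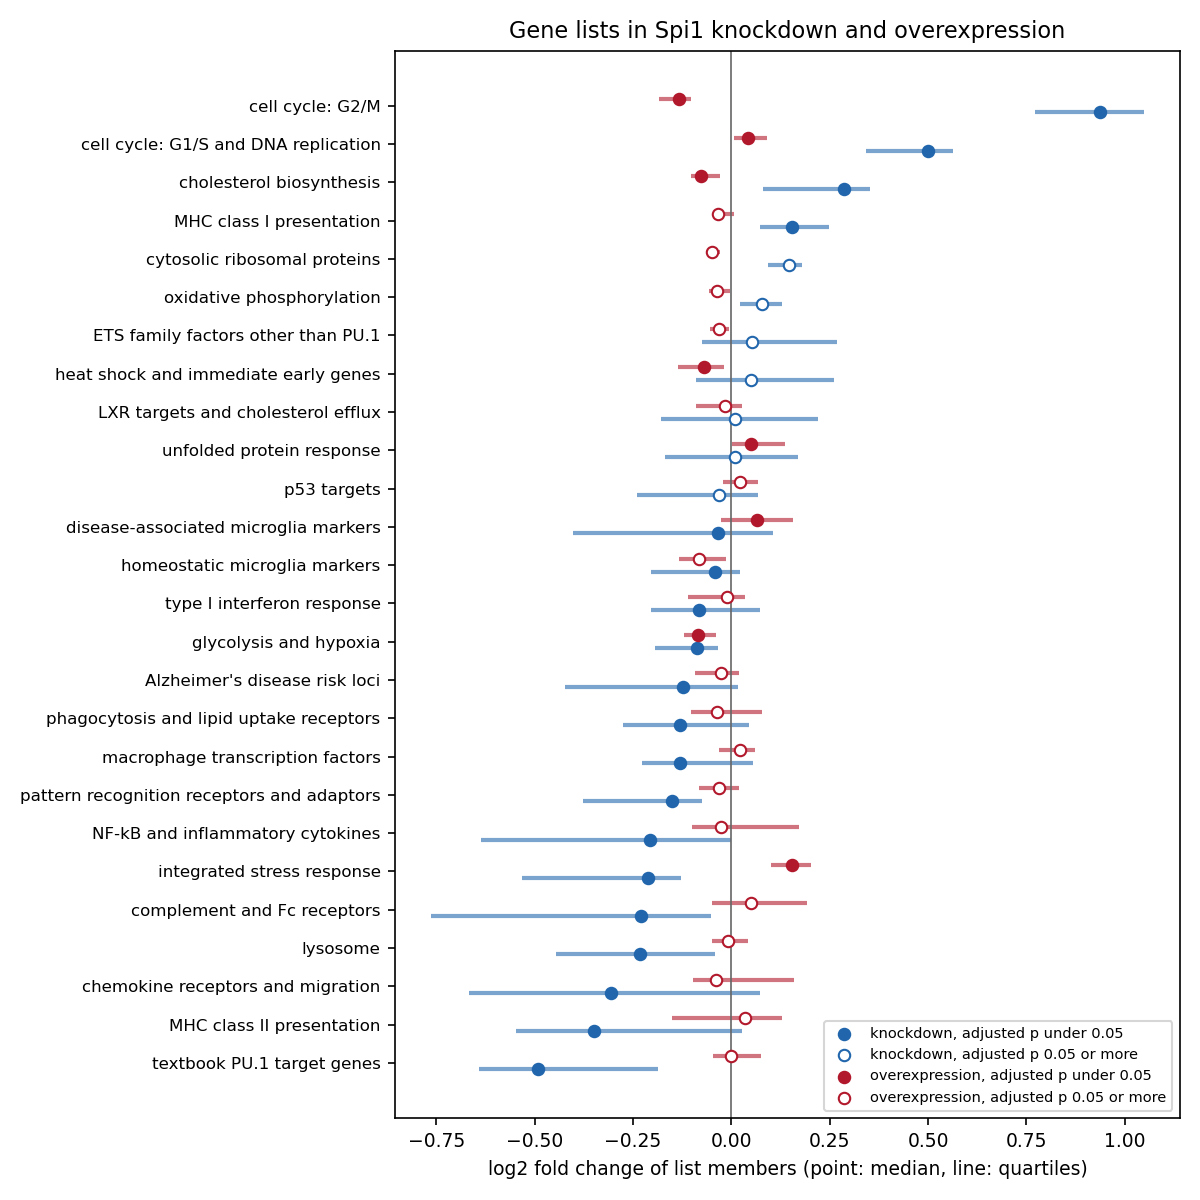
Median log2 fold change (horizontal axis, on log2(FPKM + 1)) of the tested members of 26 gene lists in Spi1 knockdown (blue) and overexpression (red), with lines from the lower to the upper quartile and filled points where camera gave a BH adjusted p under 0.05. Medians run from -0.49 for textbook PU.1 target genes to 0.94 for G2/M genes in knockdown and from -0.13 to 0.15 in overexpression.

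With Spi1 raised, 13 genes passed where same-numbered libraries were taken as pairs. Spi1 itself was higher in 3 of 3 same-numbered pairs, by 0.81 on the log2 scale (limma, BH adjusted p = 0.9999, 0.0357 with the replicate block, and 0.0357 to 1 over 9 alternatives), and reads of the cDNA could not be told from those of the endogenous gene. Mmp12, the gene of macrophage metalloelastase, averaged 4.73 ± 2.26 FPKM in the empty controls and 26.5 ± 12.4 in overexpression (SD, n = 3 each). Mmp13, a collagenase gene, averaged 0.712 ± 0.415 and 3.28 ± 1.53 FPKM, and Ccl12 averaged 15.02 ± 7.66 and 35.7 ± 13.2 FPKM. Il1rn stood at 193 ± 12.04 and 445 ± 135 FPKM and Hp at 6.26 ± 2.77 and 2.23 ± 0.368 FPKM, though neither passed a test in this experiment (limma, BH adjusted p = 0.9999 for both, and 0.115 and 0.148 with the replicate block).

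Of 11217 genes tested, limma with BH adjustment called 0, with 122 at an unadjusted p under 0.05. That test leaves the pairing by number in the spread. With the replicate block 1577 genes had an unadjusted p under 0.05, against 561 expected by chance. limma-voom also called 0, with 99 at an unadjusted p under 0.05, as did median-of-ratios scaling, with 125. With the replicate number as a block 13 genes passed, each moving 1 way in 3 of 3 pairs, with adjusted p-values in limma from 0.0348 to 0.0480 after BH adjustment. They fall outside the rule for naming genes and were chosen after their values were seen. Besides Spi1, Mmp12 (log2 fold change 2.21), Mmp13 (1.28) and Ccl12 (1.26), the higher ones were Gm5483 (1.11), Gsta2 (0.64), Evl, an actin regulator gene (0.63), Adora2b, an adenosine receptor gene (0.58), and Mir7240 (0.56). The lower ones were Ccl5, a chemokine gene (-0.57, from 2002 ± 877 to 1353 ± 597 FPKM), and the microRNA loci Mir7026, Mir3101 and Mir6946 (-0.74, -0.73 and -0.59). The 4 microRNA loci rest on few reads, at mean CPM values of 0.128 to 0.273, and the exons of Evl and Mmp12 overlap those of other genes. limma-voom with the block, added after seeing the data, called 535 genes. The 3 overexpression libraries lay outside the range of the 3 controls in 4.06% of genes, 186 above and 269 below, against 10% by chance for libraries that are not paired, as these are by number.

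The libraries of this experiment differed more by number than by group. The number accounted for 81.6% of the variance between libraries and the group for 8.61%, against 30.6% and 57.1% in the knockdown experiment, and the libraries numbered 2 against the rest accounted for 63.5%. Both libraries numbered 2 lay below the other 4 in 45 of 48 type I interferon response genes, with a median log2 difference of -0.78, and in 29 of 33 G1/S genes, with a median of -0.49. Both lay above the other 4 in 33 of 35 cytosolic ribosomal protein genes, with a median of 0.41, and in 15 of 22 integrated stress response genes, with a median of 0.31. Without the libraries numbered 2, limma with BH adjustment again called 0 genes. That fit had fewer libraries and no block, so its 0 calls cannot show that a response is absent.

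**Figure D4:**
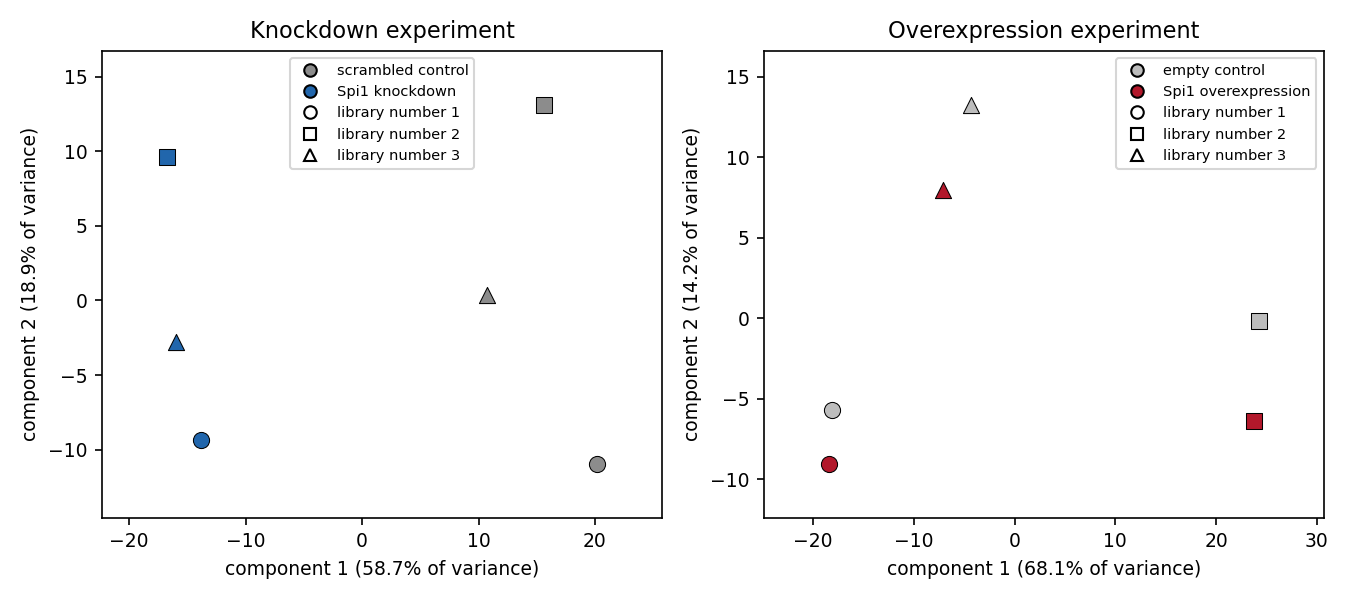
First and second principal components (axes, with their share of variance) of log2(FPKM + 1) in the knockdown and overexpression experiments, with 1 point per library, colour for the group and shape for the library number. Component 1 takes 58.7% of the variance and parts the groups in the knockdown experiment, while in the overexpression experiment it takes 68.1% and parts the libraries numbered 2 from the rest.

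Among the lists, 8 of 26 passed in camera for overexpression with small medians, and each lost its call without at least 1 library. Leaving out 1 library breaks a same-numbered pair, so these fits without the block mix the number with the group. Over 13 alternatives for each, the highest adjusted p of the 8 lists lay between 0.595 and 0.971, and 5 lists passed without empty control 3. Genes of the integrated stress response were higher in 20 of 22 members, among them Aars, an alanyl-tRNA synthetase gene, at 0.20, with a median of 0.15 (camera in limma, BH adjusted p = 2.68e-09, and adjusted p = 0.480 with an estimated correlation). The call was lost without overexpression 2 (adjusted p = 0.370). G2/M genes were lower in 32 of 33 members, among them Prc1 at -0.23, with a median of -0.13 and a lower list mean in 3 of 3 pairs (camera in limma, BH adjusted p = 1.98e-05, and adjusted p = 0.721 with an estimated correlation). This was lost without overexpression 1 (adjusted p = 0.109), overexpression 2 (0.155) or empty control 3 (0.690). Disease-associated microglia markers were higher in 19 of 28 members, among them Atp6v0d2, a proton pump gene, at 0.49, with a median of 0.07, and unfolded protein response genes in 13 of 18, with a median of 0.05 (camera in limma, BH adjusted p = 0.0105 for both, and adjusted p = 0.480 with an estimated correlation). The first was lost without empty control 1 (adjusted p = 0.309), empty control 3 (0.306), overexpression 1 (0.0633) or overexpression 2 (0.790), and the second without empty control 2 (0.103), empty control 3 (0.292), overexpression 1 (0.257) or overexpression 2 (0.0910). Genes of glycolysis and hypoxia were lower in 23 of 27 members, with a median of -0.08, and cholesterol biosynthesis genes in 20 of 23, among them Insig1 at -0.22, with a median of -0.08 (camera in limma, BH adjusted p = 0.00282 and 0.00761, and adjusted p = 0.480 with an estimated correlation for both). The glycolysis call was lost without empty control 1 (adjusted p = 0.244) or overexpression 3 (0.173), and the cholesterol call without empty control 1 (0.0976), empty control 2 (0.415) or overexpression 3 (0.771). Heat shock and immediate early genes were lower in 15 of 19 members, among them Nr4a1 at -0.40, with a median of -0.07, and G1/S genes higher in 27 of 33, with a median of 0.04 (camera in limma, BH adjusted p = 0.0211 and 0.0342, and adjusted p = 0.480 and 0.881 with an estimated correlation). The heat shock call was lost without empty control 1 (adjusted p = 0.0976), empty control 2 (0.469), overexpression 1 (0.0523) or overexpression 3 (0.488). The G1/S direction turned without empty control 2 (median -0.10, adjusted p = 0.415) or overexpression 1 (-0.04, 0.971), and the call was lost without overexpression 3 (-0.04, 0.827).

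Textbook PU.1 target genes were not among these lists, with a median of -0.000718 in overexpression, or 0.01 with median-of-ratios scaling, and 18 of 37 members above 0 (camera in limma, BH adjusted p = 0.127). The nearest to passing were Emr1 at 0.28 and Ncf4 at 0.20. With the block the cytosolic ribosomal protein genes passed as well, lower in 34 of 35 members with a median of -0.05 (adjusted p = 0.0125, and 0.373 without the block, by camera in limma with BH adjustment). With the block this list had an adjusted p = 0.730 with an estimated correlation. By gene, limma and limma-voom called 0 members of any of the 26 lists. At an unadjusted p under 0.05 limma had 3 members of the NF-kB list, 2 each of the disease-associated, chemokine receptor, Alzheimer's disease and PU.1 lists, 1 or 0 in each other list. Adjusted over the list alone, 2 NF-kB members, 1 disease-associated marker and 1 member of the chemokine receptor list passed, all higher. With the block 1 NF-kB member, lower, and 1 chemokine receptor list member, higher, passed over all genes.

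The test of the difference asked where raised and lowered Spi1 had unlike effects, so a gene that moved in knockdown alone can pass it. The overexpression effect minus the knockdown effect was 2.56 on the log2 scale for Spi1 itself, 2.68 for Il1rn, 2.31 for Il1f9, 1.98 for Cxcl2, a neutrophil chemokine gene, 1.74 for Clec7a and 1.53 for Psph. It was -4.32 for Hp, -1.51 for Uchl3 and -1.09 for Insig1. The standard errors of these 9 differences lay between 0.109 and 0.394, and their adjusted p-values in limma with BH adjustment at or below 0.00376. Msr1 differed by 1.13. Ccl12 differed by 2.82 with a standard error of 0.537 (limma, BH adjusted p = 0.0216), and the call was lost without scrambled control 2 (adjusted p = 0.0638), knockdown 2 (0.0512) or knockdown 3 (0.0639). For Uchl3, Ccl12 and Cxcl2 the knockdown level was near that of the empty controls of the other experiment. Scrambled controls that were low for Uchl3, and high for Ccl12 and Cxcl2, therefore cannot be told apart from an effect of knockdown.

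Of 11112 genes tested in both tables, 549 passed this test in limma with BH adjustment, 214 with a positive and 335 with a negative difference. With median-of-ratios scaling 599 passed, 341 positive and 258 negative, so that the larger side turned with the scaling, and with the replicate block 4662 passed. It turned also in limma-voom (383, 297), at an adjusted p of 0.01 (49, 29) and among 2-fold changes (56, 53). The same happened without scrambled control 2 (67 positive, 41 negative), knockdown 1 (114, 72), knockdown 3 (77, 40), empty control 3 (77, 44) or overexpression 1 (118, 112). The count fell to 238 without scrambled control 1, 108 without scrambled control 2, 186, 199 and 117 without knockdown 1, 2 and 3, 121 without empty control 3, and 230 and 363 without overexpression 1 and 2. Without the libraries numbered 2 it was 86, with 62 positive and 24 negative, of which 72 were among the 549.

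By list, 14 of 26 differed in camera, a test added after seeing the data, and over 19 alternatives for each the highest adjusted p lay between 0.219 and 0.621. Textbook PU.1 target genes had a median difference of 0.52, and 14 of 37 members passed, all positive, or 20 positive and 1 negative adjusted over the list alone (camera in limma, BH adjusted p = 4.35e-17, and adjusted p = 0.0239 with an estimated correlation). Lysosomal genes had a median of 0.21 with 3 of 37 members positive, or 11 adjusted over the list alone, and NF-kB genes a median of 0.25 with 4 of 32 positive, or 7 adjusted over the list alone. Their adjusted p-values, by camera in limma with BH adjustment, were 1.38e-07 and 3.85e-06, and adjusted p = 0.0242 and 0.0239 with an estimated correlation. With an estimated correlation and the replicate block, none of the PU.1, lysosome and NF-kB lists passed (adjusted p = 0.219 for each). G2/M genes had a median of -1.07 with 22 of 33 members negative, or 32 adjusted over the list alone (camera in limma, BH adjusted p = 6.16e-19, and adjusted p = 0.186 with an estimated correlation). Against the empty controls, G2/M genes stood at -0.80 in the scrambled controls and 0.11 in knockdown, so low scrambled controls may enter this difference. Cholesterol biosynthesis genes had a median of -0.35 with 3 of 23 negative, or 8 adjusted over the list alone (camera in limma, BH adjusted p = 0.000534, and adjusted p = 0.186 with an estimated correlation). Integrated stress response genes had a median of 0.36 with 2 of 21 positive, or 5 adjusted over the list alone, and complement and Fc receptor genes a median of 0.55 with 4 of 17 positive, or 4 adjusted over the list alone (camera in limma, BH adjusted p = 1.49e-07 and 3.78e-06, and adjusted p = 0.178 and 0.0794 with an estimated correlation). The other lists that passed, none of them with an estimated correlation, were those of pattern recognition, Alzheimer's disease risk, chemokine receptors, disease-associated markers, MHC class II and phagocytosis, all positive, and G1/S, which was negative. With the replicate block the positive and negative members were 27 and 2 for PU.1 targets, 22 and 3 for the lysosome, 16 and 4 for NF-kB, 15 and 1 for the stress response, and 10 and 2 for complement. The negative ones were 15 for cholesterol and 25 for G1/S, with none positive.

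Across genes, the fold changes of the 2 experiments ran against each other weakly. Over the 11112 genes tested in both, Pearson's r was -0.26 and Spearman's rho -0.20, and among the 2916 genes called in knockdown they were -0.42 and -0.32. Genes are not independent replicates, so no p-value is attached. Without overexpression 2 or empty control 3 the Pearson value moved to -0.10 or -0.12 and the Spearman value to -0.02 or -0.01. Each of these fits breaks a same-numbered pair. Of 1926 genes called higher in knockdown, 1311 (68.1%) were below 0 in overexpression, against 57.9% of all genes, and of 990 called lower, 586 (59.2%) were above 0, against 42.1% of all genes. In limma with BH adjustment 0 genes were called in opposite directions in both experiments, since 0 were called in overexpression (122 at an unadjusted p under 0.05), and limma-voom and median-of-ratios scaling gave the same. With the replicate block 5 genes fell in knockdown and rose in overexpression, against 1.18 expected for independent lists: Spi1, Ccl12, Mmp12, Evl and Gm5483, which were chosen after their values were seen. The opposite directions of Spi1 follow from the treatments, so it does not count as an excess. In the reverse direction, higher in knockdown and lower in overexpression, the block gave 0 genes against 1.22 expected.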

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

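Chosen only after the result was seen were the tests of differences between lists, those of scaling, of Spi1 level and of low scrambled controls for G2/M genes, and those of gene length and of a shared culture for the libraries numbered 2.

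These results stand out because the effect of overexpression and the effect of knockdown differed in a direct test of the difference. Spi1 was raised in 1 experiment and lowered in the other, so its own difference follows from the treatments. A gene that moved in knockdown alone also gives a difference. limma without the block called 0 genes in overexpression, so the list does not show a response to raised Spi1. Uchl3 had log2 fold changes of 1.54 in knockdown and 0.03 in overexpression, and Il1rn had -1.52 and 1.16. Uchl3 levels were alike in all groups but the scrambled controls, so low scrambled controls cannot be told apart from a rise in knockdown. Ccl12 and Cxcl2 had knockdown levels near those of the empty controls, so for them high scrambled controls cannot be told apart from a fall. By gene, 549 of 11112 passed in limma with BH adjustment. Among the named ones the difference on the log2 scale was 2.56 for Spi1, 2.82 for Ccl12, 2.68 for Il1rn, 2.31 for Il1f9, 1.98 for Cxcl2, 1.74 for Clec7a and 1.53 for Psph, and -4.32 for Hp, -1.51 for Uchl3 and -1.09 for Insig1. The Ccl12 call was lost without scrambled control 2, knockdown 2 or knockdown 3, at differences of 2.76, 2.75 and 2.76. The count was 238 without scrambled control 1, 108 without scrambled control 2, 186, 199 and 117 without knockdown 1, 2 and 3, 121 without empty control 3, and 230 and 363 without overexpression 1 and 2.

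By list, the median differences were 0.52 for textbook PU.1 target genes, 0.55 for complement and Fc receptors, 0.36 for the integrated stress response, 0.28 for MHC class II presentation, 0.28 for chemokine receptors and 0.25 for NF-kB and inflammatory cytokines. They were 0.21 for the lysosome, 0.14 for pattern recognition receptors, 0.13 for phagocytosis and lipid uptake receptors, 0.10 for disease-associated microglia markers and 0.0659 for Alzheimer's disease risk loci. The medians were -1.07 for G2/M genes, -0.44 for G1/S genes and -0.35 for cholesterol biosynthesis. These 14 lists passed in camera with a preset correlation between genes; 3 passed with an estimated correlation (PU.1 target genes, NF-kB and lysosome), and 0 with an estimated correlation and the replicate block, where the lowest adjusted p was 0.219.

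Other splits of the libraries were compared with the real ones. In knockdown 2945 genes were called, against at most 0 in the 9 other splits, with at most 451 at an unadjusted p under 0.05 (1 of 10 splits gave as many), and 19 lists, against at most 20 (2 of 10 splits gave as many); 10 splits are too few for a share under 0.05. The split with 20 lists set scrambled controls 1 and 2 with knockdown 1, and the other splits that part the 3 same-numbered pairs gave at most 14 lists. In overexpression 0 genes were called by limma in the real split (122 at an unadjusted p under 0.05, and 0 by limma-voom) and at most 0 in the others, so that 10 of 10 splits gave as many. At an unadjusted p under 0.05 the others had at most 43 genes where they part the 3 pairs and at most 3780 where they do not, which points to the structure by number. The 8 lists called stand against at most 12, in the split of empty controls 1 and 3 with overexpression 3, or at most 4 in others that part the 3 pairs, and 4 of 10 splits gave as many; these splits too are too few. With the replicate block, which was run for the splits that part the 3 pairs, the real split gave 13 genes and the 3 others at most 0, with at most 431 at an unadjusted p under 0.05 against 1577. For the difference, 3 of 100 drawn splits, from 200 possible, gave 549 genes or more. Of the drawn splits 9 keep the real knockdown grouping, with 129 to 2611 genes called, and the others gave at most 3. The share therefore rests on the knockdown grouping and does not test the difference itself. Among the 8 other splits that keep this grouping, 1 is the real overexpression grouping with its sides exchanged (140 genes), and the 4 others that part the 3 same-numbered pairs, from 3 divisions, gave 129 to 327 genes, fewer than the real split. The 2 highest, 2611 and 1326, are the same division taken either way, of empty controls 1 and 3 with overexpression 1, which does not part the pairs. It follows the standing apart of the libraries numbered 2. So few pair-parting splits cannot give a share under 0.05.

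G2/M genes were higher in knockdown, with a median log2 fold change of 0.94. The tables argue against scaling by the library total, since the median was 0.86 under median-of-ratios scaling, and against depth, since it was 0.93 after thinning each library to 24.4 megareads. The largest rise in a summed marker list of another cell type was 16.9 FPKM, for the erythroid and megakaryocyte list. The neuron and oligodendrocyte sums were higher in all 3 knockdown libraries, by 0.118 and 3.70 FPKM between the means. These values argue against a large share of reads from the 9 cell types listed. They cannot exclude a smaller or unlisted source. Low scrambled control libraries stay open as an explanation, since these stood at -0.80 against the empty controls and knockdown at 0.11, in tables normalised separately. An effect of the Spi1 level stays open too, as a hypothesis, since in overexpression the median was -0.13, with list means of -0.07, -0.24 and -0.11 in the 3 pairs.

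The libraries numbered 2 of the overexpression experiment stood apart, with 63.5% of the variance between libraries. The tables argue against scaling and against a few abundant genes, since this share was 62.5% with median-of-ratios scaling, and against gene length, since the difference correlated with length at a Spearman value of -0.0363 over 11220 genes. A culture or preparation shared by libraries of 1 number cannot be told apart from other sources, since the correlation of the deviations of the 2 libraries, 0.845, restates the pattern and the labels do not explain the numbers. The design gives no biological explanation for these numbers, and none was tested.

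More genes were called higher than lower in knockdown, 1952 against 993, with a median log2 fold change of 0.07 over all tested genes. The most abundant genes account for part of it and not for most of it. Leaving the 100 most abundant genes out of the library totals moved the median from 0.0723 to 0.0555, with 1815 genes then higher and 1101 lower. Depth accounts for little, since the median was 0.0711 after thinning. The split turned to 1251 against 1454 with median-of-ratios scaling, which takes the middle gene as unchanged, and total RNA per cell was not measured.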

How the results depend on the processing

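Chosen only after seeing the data were the trended prior, the block combined with another scaling or list test, the fits without the libraries numbered 2, and every list test of the difference. Of 103 named knockdown genes, 99 kept their call with median-of-ratios scaling and 103 with the replicate block, and 75 of 618 leave-one-out values lost it; none turned. Of 53 named differences, 49 and 53 kept it, and 228 of 634 leave-one-out values lost it. By list, leave-one-out fits lost 8 of 114 knockdown calls, 24 of 48 overexpression calls, 2 of which turned, and 0 of 168 calls of the difference. The replicate block kept the direction and call of all 19, 8 and 14 lists in camera.

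With the replicate block, counts moved from 2945 to 5081 genes in knockdown, from 0 to 13 in overexpression and from 549 to 4662 for the difference, since the pairs share deviations. The opposite calls moved from 0 to 5, and Spi1 in overexpression passed at 0.81. With the block and median-of-ratios scaling the gene counts were 4704, 12 and 4113, and with the block and limma-voom 5430, 535 and 4693. Without the libraries numbered 2 they were 449 in knockdown and 86 for the difference, with fewer samples. With 1 spread shared by all 12 libraries knockdown had 1624 genes. Stricter thresholds left 917 genes in knockdown and 78 for the difference at an adjusted p of 0.01, and 85 and 109 with at least a 2-fold change. Leave-one-out counts ran from 1458 (without knockdown 3) to 2206 (without scrambled control 3) in knockdown and from 108 (without scrambled control 2) to 585 (without empty control 1) for the difference. Knockdown counts were 1905 and 1708 without knockdown 1 and 2; those of the difference were 238 without scrambled control 1, 186, 199 and 117 without knockdown 1, 2 and 3, 121 without empty control 3, and 230 and 363 without overexpression 1 and 2. Where no reason is given, the cause was not tested.

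With an estimated correlation 0 knockdown lists, 0 overexpression lists and 3 of the difference passed, as did 0, 0 and 0 with the block as well. fry called 13, 0 and 9, and with the block 0, 0 and 20. Overexpression lists numbered 5 (without empty control 3) to 7 (without empty control 2 or overexpression 3) in leave-one-out fits. The G1/S list in overexpression ran from -0.10 (without empty control 2) to 0.23 (without overexpression 2), and was below 0 also without overexpression 1 or 3, at -0.04 each. The correlation between experiments ran from -0.34 (without overexpression 3) to -0.10 (without overexpression 2), and was -0.12 without empty control 3. These fits were without the block, so leaving out 1 overexpression or empty control library broke a same-numbered pair. Part of the difference by number then entered the group contrast. The number accounted for 81.6% of the variance in the overexpression experiment. G1/S genes had a median of -0.49 in its libraries numbered 2 against the rest. How far this accounts for the moves was not tested. Pseudocounts, low-value filters and the trended prior kept the counts of genes for knockdown, overexpression and the difference within 1.5 times, and leaving Spi1 out of the totals, run for overexpression alone, left 0. The tests planned for counts in edgeR (TMM, filterByExpr, quasi-likelihood) and DESeq2 were not run, since FPKM were deposited, and scaling by library size alone is what FPKM already holds. At 22.3 to 33.1 megareads per library, the microRNA loci named in overexpression rest on mean CPM values of 0.128 to 0.273.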

Other observations

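The test of the mirrored fold changes below was set out before its result was seen. The comparisons across the 2 tables, which a shift between the experiments would enter, were chosen only after the data were seen.

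Markers of other cell types were low or few. Of the lists, neuron, fibroblast and B cell markers had 0 genes at a mean of 1 FPKM or more, of 12, 14 and 10, by level alone and with no test; the neuron sum was 0.336 FPKM in scrambled controls and 0.454 in knockdown. The astrocyte list had 1 of 11, Aldoc, an enzyme gene of glycolysis, at 54.3 FPKM, and its sum was 61.6 FPKM in scrambled controls and 43.7 in knockdown. The oligodendrocyte list had 1 of 11, Cnp at 10.03 FPKM, and its sum was 8.40 and 12.1 FPKM. In the neuron, astrocyte and oligodendrocyte lists the 3 knockdown libraries lay outside the range of the controls, to which chance gives 10%. The T cell list had 4 of 12 (highest Il7r, an interleukin receptor gene, at 25.6 FPKM) with sums of 54.7 and 52.4 FPKM. The erythroid and megakaryocyte list had 2 of 12 (highest Pf4, a chemokine gene, at 90.5 FPKM) with sums of 107 and 124 FPKM. The neutrophil list had 4 of 13 (highest Lcn2, a siderophore-binding protein gene, at 31.6 FPKM) with sums of 62.2 and 69.3 FPKM, and the dendritic cell list 1 of 9 (Batf3 at 11.8 FPKM) with sums of 11.9 and 13.6 FPKM.

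Set across the 2 tables, type I interferon response genes stood above the empty controls in both groups of the knockdown experiment, with medians of 0.47 in scrambled controls, where 0 of 48 members were below, and 0.38 in knockdown. Empty control 2 lowers this reference, since both libraries numbered 2 of that experiment lay below the other 4 in 45 of 48 of these genes, with a median of -0.78. Csf3 stood at 25.6, 7.91, 7.94 and 14.1 FPKM in scrambled controls, knockdown, empty controls and overexpression, Cxcl2 at 67.0, 26.5, 27.2 and 43.7 FPKM, and Nos2 at 87.4, 22.3, 21.7 and 30.5 FPKM. Il1f9 stood at 12.6, 2.90, 11.9 and 17.9 FPKM, and Clec4n at 15.6, 3.14, 17.3 and 33.1 FPKM. Of 1926 genes called higher in knockdown, 65.8% had knockdown levels nearer to the empty controls than the scrambled controls were, as did 33.2% of 990 called lower. Among called genes that changed by 1 or more on the log2 scale, the shares were 87.2% of 39 higher and 30.2% of 43 lower. Mmp12 fell in knockdown with the replicate block (log2 fold change -1.88, limma with BH adjusted p = 0.00366, lower in 3 of 3 pairs) and did not pass without it (adjusted p = 0.136).

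A hypothesis was that the Spi1 level sets mirrored fold changes in the 2 experiments. The Pearson value across genes was -0.26 for the real overexpression split, and the largest size among the other splits that part the 3 pairs was 0.171, with 4 such splits in all. So few splits give no share under 0.05, and an effect of the Spi1 level cannot be told apart from a chance arrangement by this test.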
